A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

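The samples were cultures of the budding yeast Saccharomyces cerevisiae in 4 groups of 2 libraries: a parent strain and 3 strains carrying a mutant allele of a Mediator subunit gene, called med7, med21 and med10 here for the full allele names that the figures give. The labels give the same 2 barcodes to the med7 and the med10 libraries, and no sequencing run, so a batch difference between these groups could not be tested. Per the labels' protocols, cells were grown at 30 °C in rich glucose medium (YPD) to an OD600 of 0.8 and labelled for 6 min with 5 mM 4-thiouracil, a uracil analogue that is built into RNA made during the pulse. Per the same protocols, spike-in RNA was added before lysis, the labelled RNA was purified from total RNA, and libraries were made with the NuGEN Ovation Universal kit from 100 ng of RNA. The measurement therefore weights RNA made in a 6 min window, together with any unlabelled RNA carried through the purification, whose share was not measured in the counts used here.

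The deposited files hold raw read counts per transcript, 1 file per library, and a transcript annotation shared by all of them. Per the submitters' processing notes, STAR 2.3.0, SAMtools and HTSeq were used with genome builds sacCer3 and R64; the strand setting, the counting mode and the treatment of reads with several matches are not given in the sources used here. The annotation lists 6030 transcripts: 4928 transcripts of open reading frames, 500 stable unannotated transcripts (SUTs), 433 Xrn1-sensitive unstable transcripts (XUTs) and 169 cryptic unstable transcripts (CUTs). Of the coding transcripts, 4842 matched a gene of the RefSeq annotation of R64 by systematic name, each of these contained the coding interval of its gene, and 86 did not match. Coordinates below are those of the deposited annotation on R64, and they span the whole annotated transcript, untranslated regions and any introns included. Transcript lengths are these spans. Between 5.35% and 6.80% of the counted reads lay, by transcript position, where another transcript covers the opposite strand, while 0.0544% to 0.193% were set aside as ambiguous, as a counter does that keeps the strands apart. The read counts for spike-in RNA were not analysed here, so all values are relative to the other transcripts of the same library, and a change of the total amount of RNA made per cell cannot be seen.

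Counts assigned to transcripts came to 18409345 and 17595372 in the parent libraries, 10962170 and 23629303 in med7, 20284344 and 14243200 in med21, and 21190842 and 19594321 in med10 (replicate 1, then replicate 2). The counter assigned a further share of the reads to no annotated transcript, and opposite-strand reads are among them if strands were kept apart. This share was 32.7% and 33.5% in parent, 49.5% and 37.7% in med7, 36.3% and 34.3% in med21, and 34.7% and 34.7% in med10. These reads, and the other 4 tallies kept by the counter for reads without a transcript, entered neither library sizes nor tests.

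The counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after TMM scaling and removal of 284 low transcripts with filterByExpr at a minimum count of 10, which left 5746. All 8 libraries entered 1 fit with a term per group and 4 residual degrees of freedom, so the groups share 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method, and transcripts with an adjusted p under 0.05 count as changed; every adjusted p of a single gene below is from this test unless another tool is named. Fold changes are those of the fit at its default prior count, and their standard errors (SE) were computed from the fold change and its F statistic. A prior count of 2 entered only the log2 CPM per library, which camera and the comparisons of single libraries used. Levels are in CPM scaled by TMM, given as mean ± SD of n = 2 libraries. Both libraries of a group are separate samples in the labels, but nothing says that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. On simulated counts for 5746 transcripts with 200 changed ones, the procedure found 58%, 53% and 54% of 2-fold changes and 88%, 89% and 87% of 4-fold changes in med7, med21 and med10, with 74, 0 and 0 false calls.

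Groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule takes, for each mutant against parent, the 10 genes in each direction with the largest fold change among those past the threshold, with a mean log2 CPM of at least 3 and both mutant libraries beyond both parent libraries. It adds MED7, SRB7 (the gene of Med21), NUT2 (the gene of Med10), HSP82 and HSC82, the 2 to 4 members of each gene list with the smallest adjusted p, 5 genes per direction for each pair of mutants, and 10 per direction for changes shared by all 3 mutants. NUT2 was not analysed here. Of the 23 lists, 1 is not reported here, although it counts among the list tests. The others cover heat shock, general stress, ribosomal protein, ribosome biogenesis, Gcn4 regulon, sulfur and methionine, phosphate, iron and copper, glucose-repressed and galactose, glycolysis, respiration, MATa and pheromone, MATalpha, meiosis, cell wall, cell cycle, histone, sterol, endoplasmic reticulum folding, proteasome, Mediator, and RNA polymerase II and general transcription factor genes. The phosphate list was kept as fixed, although its member CTF19 encodes a kinetochore protein. Listed genes that the annotation lacks were not counted. This left 8 meiosis and sporulation genes, a minority of those listed, 17 MATa and pheromone genes and 4 MATalpha markers. Results for these lists cover only the members present. Lists with at least 5 measured members, all but the MATalpha markers, were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01 between genes, against the other genes, and the p-values were adjusted over the 66 tests of 22 lists in 3 mutants. Camera with an estimated correlation was run beside it, and fry, which tests whether a list changed at all and not whether it changed more than other genes. Members past the threshold were counted over all genes tested and, in a second count, adjusted over the list alone.

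Alternatives were other scalings (RLE, upper quartile, library size alone), DESeq2 1.42.0, limma-voom, a robust fit, other low-count filters, coding transcripts only, the replicate number as a block, only the groups compared, each library left out, and stricter thresholds. A fit without both med7 libraries and a correction for transcript length were added after seeing the data. The correction used a trend over length in each library, fitted over all transcripts together, most of them coding. Near-identical gene copies, such as HXT6 and HXT7, HSP82 and HSC82, the histone gene pairs and the ribosomal protein gene pairs, can exchange reads, and their separate values are uncertain.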

Results

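Newly made RNA was measured in a parent strain of budding yeast and in 3 strains with mutations in Mediator, the protein complex that links gene-specific activators to RNA polymerase II. Med7, Med21 (gene SRB7) and Med10 (gene NUT2) belong to its middle module. In this text med7, med21 and med10 stand for the mutant alleles whose full names the figures give. None is described as a deletion. The comparisons ask how each allele affects transcription across the genome. Each group had n = 2 libraries with 10962170 to 23629303 assigned counts, and 5746 transcripts were tested.

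The transcripts of the mutated genes do not check the labels, since the alleles are not described as deletions. MED7 (YOL135C, chromosome XV, 69216 to 70068, minus strand) stood at 31.4 ± 0.0607 CPM in parent, 30.7 ± 0.144 in med7, 26.8 ± 1.81 in med21 and 22.6 ± 1.05 in med10. It passed the threshold in none of the 3 mutants (edgeR adjusted p = 0.886, 0.427 and 0.0852). SRB7 (YDR308C, chromosome IV, minus strand) stood at 13.5 ± 1.69 CPM in parent and did not pass in med7, med21 or med10 (adjusted p = 0.210, 0.846 and 0.425). All genotype labels include hsp82- DHSE-lacZ, and they do not say whether this is a reporter beside an intact HSP82, so what the HSP82 counts measure is uncertain. HSP82, which encodes the heat-inducible Hsp90 chaperone, was counted at 5889 ± 23.2 CPM in parent. HSP82 (YPL240C, chromosome XVI, 96408 to 98681) fell in med7 by 0.62 on the log2 scale (SE 0.19, adjusted p = 0.0238) and its constitutive relative HSC82 rose by 0.82 (SE 0.22, adjusted p = 0.0124); neither passed in med21 or med10. The 2 genes are close in sequence, so their separate values are uncertain.

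The replicates differed in how closely they agreed. The SD of the log2 difference between replicates over 5746 transcripts was 0.27 in parent, 0.37 in med21 and 0.23 in med10, and 0.92 in med7, where 816 transcripts (14.2%) lay more than 2-fold apart. Because 1 estimate of the spread serves all groups, the med7 libraries widen it for the others, and counts without them are given beside those for med21 and med10. For med7 itself that estimate is narrow: the common dispersion was 0.0302, against a median of 0.0553 over the med7 libraries alone. P-values of comparisons with med7 are therefore likely too small. On simulated counts med7 against parent gave 74 false calls, and med21 and med10 gave 0 each. Counts of list members in med21 and med10 also move with the scaling, the length correction and the replicate block, as from 5 to 12 respiration genes that rose in med10 with library size alone.

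Mating-type genes set the med7 libraries apart, although all genotype labels read MATa. In parent, med21 and med10 the genes of alpha cells were expressed: STE3, the receptor for a-factor, at 367 ± 32.8 CPM in parent, MF(ALPHA)1, the precursor of alpha-factor, at 340 ± 7.93, AFB1 at 217 ± 10.6, and SAG1, the alpha-agglutinin. In med7 MF(ALPHA)1 fell to 0.879 and 0 CPM and STE3 to 2.11 and 0 CPM (replicates 1 and 2). AFB1 fell 63.7-fold and SAG1 5.41-fold, so that 4 of the 4 measured MATalpha markers fell (median log2 fold change −7.41). Genes of a cells rose there: MFA1 and MFA2, which encode a-factor, 36.0-fold and 43.6-fold, BAR1, the protease that degrades alpha-factor, 36.0-fold, and STE2, the receptor for alpha-factor, 17.5-fold. AGA2, part of a-agglutinin, had 1 and 2 counts in parent and 137 and 323 counts in med7 (adjusted p = 0.000265). ASG7, also specific to a cells, did not pass (log2 fold change 0.25, adjusted p = 0.803). STE4 and GPA1, expressed in haploid cells of both types, did not pass either in med7 (adjusted p = 0.212 and 0.0924). AGA2, ASG7, STE4 and GPA1 were chosen after their values were seen. URA3 (YEL021W, chromosome V), which encodes orotidine-5'-phosphate decarboxylase and is ura3 in all genotype labels, rose 11.3-fold in med7, from 88.8 ± 1.36 to 1000.5 ± 160 CPM. All comparisons of med7 with another group below include these differences. The fall of the alpha-specific genes argues against loss of repression of a-specific genes by the allele alone. Whether another effect of the allele or another difference between the strains causes these differences was not tested.

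**Figure D1:**
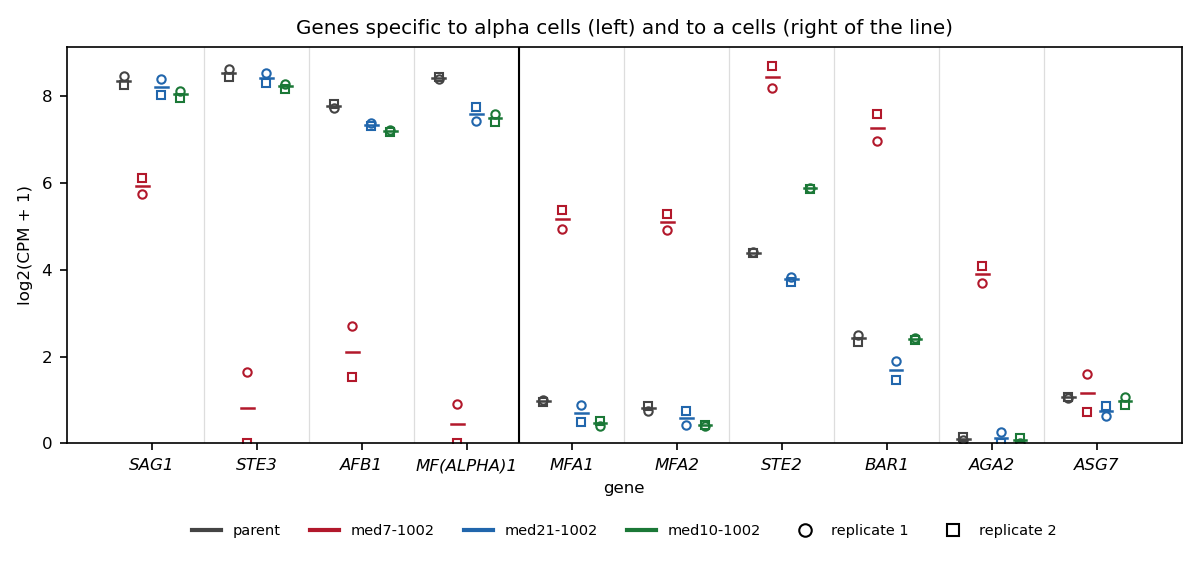
Level of 10 mating-type-specific genes in each library, as log2(CPM + 1). Circles and squares are replicates 1 and 2, bars are group means, and genes of alpha cells stand left of the line; the med7 libraries are low for all 4 alpha-cell genes and high for MFA1, MFA2, STE2, BAR1 and AGA2.

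In med7 the largest rises outside the mating-type genes were those of HSP12, a membrane-associated stress protein, 61.6-fold (log2 5.94, SE 0.42, adjusted p = 1.65e-05), and PUT4, the proline permease, from 14.6 ± 0.154 to 858 ± 212 CPM (58.7-fold, adjusted p = 2.68e-06). The ribosomal protein genes RPL41B (27.9-fold) and RPL23B (15.1-fold) and the histone H2A gene HTA2 (16.2-fold, from 18.1 ± 1.10 to 294 ± 87.2 CPM) followed. The largest falls were those of ARO10, a decarboxylase of the Ehrlich pathway of amino acid breakdown, from 2543 ± 28.2 to 84.0 ± 59.4 CPM (30.1-fold), SEO1, a putative permease, 24.8-fold, QDR2, a multidrug transporter, 10.8-fold, and IRC15, 8.13-fold. The noncoding transcripts SUT292 (10.4-fold), XUT_8F-92 (9.74-fold) and SUT726 (9.20-fold) were also among the 10 with the largest falls.

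Across all 5746 transcripts, 2790 differed between med7 and parent, 1489 higher and 1301 lower, 1325 of them by at least 2-fold (edgeR adjusted p under 0.05). With library size alone as scaling the split was 1279 higher and 1710 lower, and the median over all transcripts moved by −0.11 on the log2 scale. With only the 2 groups compared in the fit, 1902 transcripts differed, 1086 higher and 816 lower. Without parent replicate 1 the count was 1847.

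Of the 135 ribosomal protein genes measured, 133 rose in med7, also 133 when adjusted over the list alone, with a median log2 fold change of 1.86 (camera adjusted p = 1.54e-34; adjusted p = 0.494 with an estimated correlation). RPS22A (2.75), RPL15A (2.85), RPL9B (2.32) and RPS7A (2.65) had the smallest adjusted p. Transcripts up to 500 nt stood at a median log2 difference from the parent mean of 1.06 in med7 replicate 1 and −0.11 in replicate 2. Longer ones up to 1000 nt stood at 0.65 and 0.22, and the ribosomal protein transcripts have a median annotated span of 937 nt, any introns included. After the length correction, which uses these spans, 129 ribosomal protein genes rose with a median of 1.55. Without med7 replicate 1 their median was 1.83. Whether a different share of unlabelled RNA in the med7 libraries adds to this rise was not tested. Among 46 respiration genes 44 rose (44 adjusted over the list alone; median 1.64, camera adjusted p = 1.35e-14; adjusted p = 0.469 with an estimated correlation). They were led by COX12 of cytochrome c oxidase (2.40) and the ATP synthase genes ATP5 (1.97), ATP4 (1.83) and ATP3 (1.84). Of 11 histone genes 10 rose (10 adjusted over the list alone, where 1 fell), with a median of 1.65 (camera adjusted p = 0.000155; adjusted p = 0.524 with an estimated correlation). HTA2 (4.01), HHT1 (3.44), HHF1 (3.26) and HTB1 (1.80) were among those that rose. Of 32 proteasome genes 25 rose and 1 fell, the same counts when adjusted over the list alone (median 0.82, camera adjusted p = 6.00e-07; adjusted p = 0.524 with an estimated correlation), with PRE7 at 1.34 and PRE9 at 1.08. Of 25 sterol genes, which act in ergosterol synthesis and its control, 20 rose and 2 fell (21 and 2 adjusted over the list alone; median 1.09, camera adjusted p = 1.40e-05; adjusted p = 0.577 with an estimated correlation), with ERG2 at 1.78 and ERG3 at 1.65. After the length correction 8 histone genes rose and 1 fell (median 1.10). Respiration genes then numbered 42 and 1 (median 1.39), proteasome genes 23 and 1 (0.64) and sterol genes 22 and 1 (1.13).

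Among the lists that were lower in med7, 19 of 21 sulfur and methionine genes fell (19 adjusted over the list alone; median −1.16, camera adjusted p = 1.60e-06; adjusted p = 0.568 with an estimated correlation). SAM3, an S-adenosylmethionine permease, stood at −2.47, MMP1, an S-methylmethionine permease, at −1.77 and MET13, a methylenetetrahydrofolate reductase, at −1.50. Of 25 iron and copper genes 14 fell and 5 rose (15 and 5 adjusted over the list alone; median −0.99, camera adjusted p = 0.00153; adjusted p = 0.469 with an estimated correlation). FRE4, a ferric reductase (−2.75), TIS11, which promotes decay of mRNAs under iron shortage (−2.92), and ENB1, a siderophore transporter (−1.53), fell, while FIT3, a cell wall mannoprotein that retains siderophores, rose (2.55). Of 30 heat shock genes 17 fell and 7 rose (17 and 8 adjusted over the list alone; median −0.54, camera adjusted p = 0.0247; adjusted p = 0.674 with an estimated correlation). CUR1 (−1.97) and the mitochondrial chaperone gene HSP78 (−1.99) fell, whereas HSP12 (5.94) and HSP26 (2.92), which are also general stress genes, rose. The heat shock call was lost without med7 replicate 1 (adjusted p = 0.107) and with the length correction (adjusted p = 0.0626). Of 8 meiosis and sporulation genes 5 fell, RED1 (−1.37), IME1 (−1.50) and DIT1 (−1.45) among them, and SPS4 alone rose (3.01), the same counts when adjusted over the list alone. With the length correction 3 fell and 1 rose. The median was −1.12, against −1.57 without med7 replicate 1 and −0.89 with the length correction. As a set these genes were called lower (camera adjusted p = 0.0417, or 0.647 with an estimated correlation). This call was lost without parent replicate 2 (adjusted p = 0.0847), med7 replicate 2 (0.120) or med10 replicate 1 (0.0740), with library size alone (0.117) and with the length correction (0.118).

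Weaker calls in med7 went to 33 RNA polymerase II and general transcription factor genes, of which 18 rose and 2 fell (19 and 2 adjusted over the list alone; median 0.42, camera adjusted p = 0.0173; adjusted p = 0.568 with an estimated correlation), with TFB5 at 2.72 and RPB10 at 1.48. Of 50 amino acid biosynthesis genes of the Gcn4 regulon 24 rose and 9 fell (25 and 9 adjusted over the list alone; median 0.42, camera adjusted p = 0.0417; adjusted p = 0.831 with an estimated correlation). GDH1 (2.45), ARG1 (1.97) and GLN1 (1.72) rose and ARO9, an aromatic aminotransferase, fell (−2.53). Of 81 ribosome biogenesis genes 23 rose and 2 fell (19 and 1 adjusted over the list alone; median 0.29, camera adjusted p = 0.0256; adjusted p = 0.674 with an estimated correlation). The Gcn4 call was lost without med7 replicate 2 (adjusted p = 0.446) or either med21 replicate (0.0511 and 0.0502), and the ribosome biogenesis call without parent replicate 1 (0.0576) or med7 replicate 1 (0.0701) and with library size alone (0.0658). The remaining lists were not called as sets; glycolysis genes passed without parent replicate 1 (0.0468), med7 replicate 1 (0.0117), med10 replicate 1 (0.0331) or med10 replicate 2 (0.0470), with library size alone (0.0162) and with the length correction (0.0385), and general stress genes without med7 replicate 1 (0.00989). Glucose-repressed and galactose genes passed with the length correction (0.0332). Fry, which tests a list against no change and not against the other genes, gave an adjusted p of 0.0140 for them and 0.0284 for MATa and pheromone genes. General stress genes numbered 11 that rose and 3 that fell among 31, glycolysis and fermentation genes 9 and 3 among 19, glucose-repressed and galactose genes 11 and 5 among 30, and members of the phosphate list 7 and 4 among 18. HXT7 (2.89), CYB2 (2.55), HXT6 (2.18) and HXT2 (1.89) were among the glucose-repressed genes that rose. Adjusted over the list alone these were 11 and 3, 11 and 3, 11 and 5, and 7 and 4. Of 29 cell cycle genes 6 rose, such as the G1 cyclin gene PCL1 (2.50), and 12 fell, such as CDC20 (−0.91) and the mitotic cyclin gene CLB1 (−1.48); their median (−0.24) and mean (0.02) differed in sign, and the median was 0.06 with the length correction. Of 26 cell wall genes 5 rose and 4 fell, of 16 endoplasmic reticulum folding genes 4 and 3, and of 20 Mediator subunit genes 3 and 5, with SRB2 at 1.43 and NUT1 at −0.61. Adjusted over the list alone these were 6 and 12, 4 and 4, 4 and 3, and 3 and 5. The 17 MATa and pheromone genes held 5 that rose and 2 that fell, also when adjusted over the list alone, and their median (−0.18) and mean (1.27) differed in sign. The counts of this paragraph depend on single med7 libraries and on the scaling. Without replicate 1, against without replicate 2, the numbers that rose and fell were 22 and 3 against 19 and 7 for polymerase and general transcription factor, 34 and 8 against 23 and 16 for Gcn4 regulon and 35 and 9 against 37 and 13 for ribosome biogenesis genes. General stress, glycolysis and glucose-repressed genes gave 20 and 3 against 11 and 11, 14 and 3 against 9 and 5, and 14 and 7 against 13 and 7. The counts were 10 and 3 against 8 and 5 for phosphate, 9 and 10 against 5 and 14 for cell cycle and 14 and 4 against 5 and 11 for cell wall genes. They were 6 and 3 against 4 and 8 for endoplasmic reticulum folding, 4 and 5 against 5 and 10 for Mediator and 6 and 4 against 5 and 6 for MATa and pheromone genes. Library size alone gave 21 and 11 for ribosome biogenesis, 13 and 5 for polymerase and general transcription factor, 1 and 8 for Mediator and 5 and 7 for MATa and pheromone genes. It gave 11 and 5 for general stress, 11 and 5 for glycolysis and fermentation and 4 and 5 for endoplasmic reticulum folding genes. Upper-quartile scaling gave 20 and 10 for ribosome biogenesis genes, and the length correction 38 and 2 for these and 9 and 5 for cell wall genes. Without med7 replicate 1 the medians were 0.62 for Gcn4 regulon and 0.17 for ribosome biogenesis genes.

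In med21 PUT4 rose 58.3-fold, to 852 ± 25.1 CPM (log2 5.86, SE 0.22, adjusted p = 5.16e-06). The stress genes HSP12 (12.7-fold), CTT1, which encodes cytosolic catalase (7.71-fold, 41.4 ± 3.63 to 319 ± 36.6 CPM), DDR2 (log2 2.81) and the small heat shock gene HSP26 (5.45-fold) rose. So did the glucose transporter genes HXT4 (10.3-fold, 103 ± 2.90 to 1063 ± 166 CPM, adjusted p = 1.42e-05), HXT7 (9.86-fold) and HXT6 (5.23-fold), the last pair being near-identical and uncertain. NCA3 (5.99-fold) and the sporulation gene SPS4 (5.81-fold) followed. Falls were led by ARO10 (19.5-fold), SEO1 (10.4-fold), IMD2, an inosine monophosphate dehydrogenase (9.78-fold), ARO9 (6.45-fold), QDR2 (4.61-fold), SAM3 (3.82-fold) and ESBP6 (3.78-fold). Among noncoding transcripts the largest falls were those of SUT116 (4.65-fold), SUT429 (4.58-fold) and SUT406 (3.84-fold).

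Between med21 and parent 448 transcripts differed, 223 higher and 225 lower, 186 by at least 2-fold (edgeR adjusted p under 0.05). Without the med7 libraries the count was 1694, 844 higher and 850 lower. Leaving out any 1 of the 8 libraries moved it by more than 1.5 times, from 107 without parent replicate 1 to 1695 without med7 replicate 1.

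Of 31 general stress genes 17 rose and 1 fell in med21 (23 and 1 adjusted over the list alone; 23 and 2 without the med7 libraries), with a median of 1.07 (camera adjusted p = 5.27e-11; adjusted p = 0.524 with an estimated correlation). Besides HSP26 (2.45) they included the glycogen synthesis genes GSY1 (2.24) and GLC3 (2.17) and the cell wall gene SPI1 (1.74). Of 46 respiration genes 23 rose (38 adjusted over the list alone; 42 without the med7 libraries, where 1 fell), with a median of 0.70 (camera adjusted p = 2.78e-19; adjusted p = 0.469 with an estimated correlation). Among them were COX12 (1.23), CYT1, cytochrome c1 (1.13), RIP1, the Rieske protein (1.07), and HAP4, the regulatory subunit of the activator of respiratory genes (2.02). Of 11 histone genes 7 rose, 7 also when adjusted over the list alone and 7 without the med7 libraries (median 0.69, camera adjusted p = 1.25e-05; adjusted p = 0.524 with an estimated correlation). HTA2 stood at 2.19, HTB2 at 1.22, HHF1 at 1.78 and HHT1 at 1.79. Of 30 glucose-repressed and galactose genes 7 rose (8 adjusted over the list alone; median 0.06, camera adjusted p = 0.0366; adjusted p = 0.577 with an estimated correlation), HXT4 (3.37) and HXT2 (1.61) among them; without the med7 libraries 10 rose and 5 fell. That call was lost without med7 replicate 1 (adjusted p = 0.0701), med7 replicate 2 (0.0872), med21 replicate 1 (0.187) or med10 replicate 1 (0.0551), with library size alone (0.0602) and with the length correction (0.0687).

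Small shifts in med21 were called for 135 ribosomal protein genes, of which 7 rose (1 adjusted over the list alone; median 0.25, camera adjusted p = 1.93e-06; adjusted p = 0.647 with an estimated correlation), RPS9A (0.78) and RPS17B (0.75) among them. The same holds for 32 proteasome genes, of which 2 rose, RPN8 (0.55) and PUP2 (0.52), also when adjusted over the list alone (median 0.26, camera adjusted p = 3.30e-06; adjusted p = 0.524 with an estimated correlation). It also holds for 19 glycolysis and fermentation genes, of which 2 rose, TDH1 (0.99) and HXT1 (0.81), and 1 fell, PDC5 (−0.60) (8 and 1 adjusted over the list alone; median 0.32, camera adjusted p = 0.000308; adjusted p = 0.649 with an estimated correlation). Of 25 iron and copper genes 9 fell and 1 rose (11 and 2 adjusted over the list alone; median −0.40, camera adjusted p = 0.000882; adjusted p = 0.469 with an estimated correlation). TIS11 stood at −1.63, FRE3 at −1.06 and the vacuolar transporter gene FTH1 also lower (adjusted p = 0.00221). Of 21 sulfur and methionine genes 3 fell, SAM3 (−1.93), MMP1 (−1.46) and MET28 (−0.92), and 4 when adjusted over the list alone (median −0.33, camera adjusted p = 0.000451; adjusted p = 0.647 with an estimated correlation). Of 30 heat shock genes 5 fell, CUR1 (−1.29) and AHA1 (−0.92) among them, and 2 rose, HSP26 and HSP12 (6 and 2 adjusted over the list alone; median −0.14, camera adjusted p = 0.0270; adjusted p = 0.674 with an estimated correlation). The heat shock call was lost without parent replicate 1 (adjusted p = 0.0656) or med21 replicate 1 (0.0755). With the med7 libraries left out, the counts that rose and fell were 43 and 4 for ribosomal protein, 18 and 0 for proteasome, 11 and 1 for glycolysis and fermentation, 4 and 12 for iron and copper, 2 and 12 for sulfur and methionine and 3 and 10 for heat shock genes.

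Among the lists not called in med21, 5 cell cycle genes rose, with the G1 cyclin genes CLN1 (1.95) and PCL2 (1.17), and 1 fell, CLB1 (−1.27); the list passed without med21 replicate 2 (adjusted p = 0.0261). The sterol list passed without parent replicate 1 (adjusted p = 0.0489), and the MATa list (0.0420) and the polymerase list (0.0314) without med21 replicate 1. Of 50 Gcn4 regulon genes 3 rose, with ARG1 at 1.27 and GDH1 at 0.97, and 5 fell, with ARO9 at −2.69 and ARG4 at −0.98. Of 18 phosphate genes 1 rose, GPP2 (1.95), and 2 fell, PHO89 (−1.10) and PHO5 (−1.17). SPS4 (2.54) and IME2 (0.71) rose and RED1 (−0.70) fell among 8 meiosis genes, SPI1 (1.74) and TIP1 (1.11) rose and HSP150 (−0.82) fell among 26 cell wall genes (median −0.03, mean 0.08). PRM4 (−0.82) and PRM5 (−0.51) fell among 17 MATa and pheromone genes. Adjusted over the list alone, the counts that rose and fell were 7 and 1 for cell cycle, 3 and 8 for Gcn4 regulon, 2 and 3 for phosphate, 2 and 4 for meiosis, 2 and 1 for cell wall and 0 and 3 for MATa and pheromone genes. Single genes passed among sterol genes (ERG5, 0.78), ribosome biogenesis genes (REI1, −0.55) and RNA polymerase II and general transcription factor genes (SUB1, 0.79); adjusted over the list alone, SUB1 did. No Mediator subunit gene of 20, endoplasmic reticulum folding gene of 16 or MATalpha marker of 4 passed the edgeR threshold, over all genes or adjusted over the list alone; 3, 2 and 1 had an unadjusted p under 0.05, and the counts were 0, 2 and 0 with DESeq2 and 0, 0 and 1 with limma-voom. With the med7 libraries left out, they were 9 and 4 for cell cycle, 8 and 15 for Gcn4 regulon, 5 and 3 for phosphate, 2 and 5 for meiosis, 7 and 7 for cell wall and 3 and 5 for MATa and pheromone (of 16) genes. For the other lists of this paragraph they were then 6 and 1 for sterol, 4 and 3 for ribosome biogenesis, 6 and 0 for polymerase and general transcription factor, 1 and 2 for Mediator, 1 and 2 for endoplasmic reticulum folding and 0 and 2 for MATalpha genes.

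**Figure D2:**
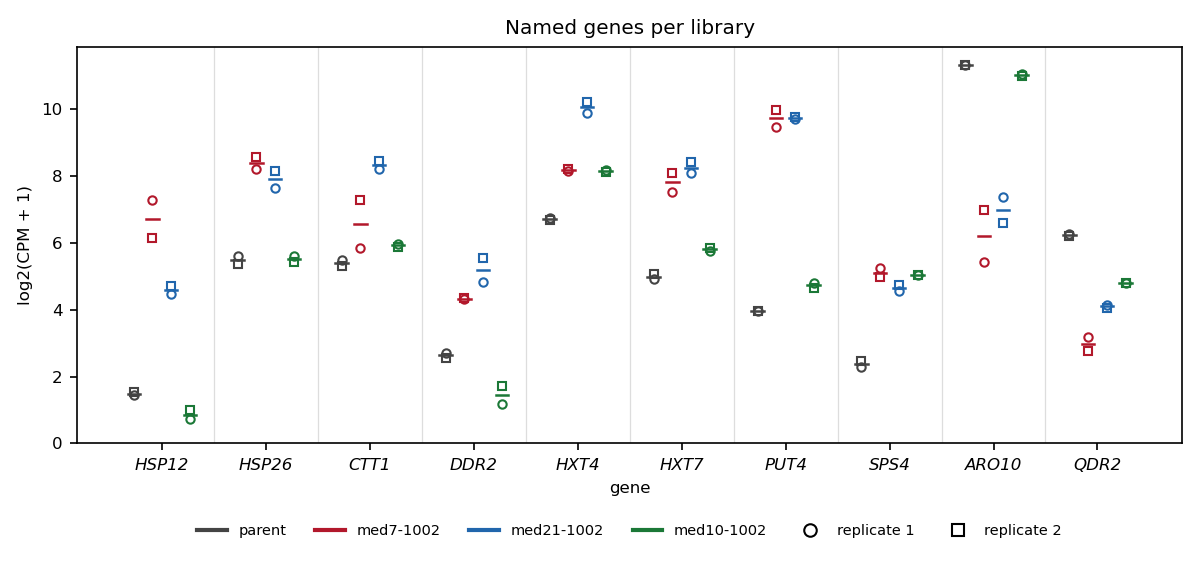
Level of 10 named genes in each library, as log2(CPM + 1), with circles and squares for replicates 1 and 2 and bars for group means. HXT4 lies between 946 and 1180.5 CPM in med21. DDR2 lies below both parent libraries in med10.

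In med10 the largest rises were those of SPS4 (7.72-fold, 4.15 ± 0.453 to 32.1 ± 0.0614 CPM, adjusted p = 0.000426), ULI1 (5.72-fold), the ribosomal protein gene RPL22B (4.12-fold, 40.0 ± 3.15 to 164 ± 1.10 CPM), YIR042C (4.08-fold) and NCA3 (4.02-fold). The other 5 were SUT674 (6.60-fold, 12.1 ± 0.853 to 80.2 ± 5.32 CPM, adjusted p = 0.000177), SUT065 (3.93-fold), SUT430 (3.89-fold), SUT063 (3.59-fold) and SUT692 (3.40-fold), which lies opposite GAL2. The largest falls were those of RPI1, a putative transcriptional regulator (4.03-fold, 108 ± 7.61 to 26.8 ± 0.286 CPM, adjusted p = 0.000720), DDR2 (2.92-fold), the cell wall gene HPF1 (2.81-fold), TIS11 (2.80-fold), QDR2 (2.77-fold), the iron permease gene FTR1 (2.66-fold, adjusted p = 0.00137), the GATA-type activator gene GAT1 (2.49-fold) and BDF2 (2.38-fold). The noncoding XUT_5R-168 (2.66-fold) and SUT485 (2.42-fold), the latter opposite ARO10, completed these 10.

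Between med10 and parent 434 transcripts differed, 283 higher and 151 lower, 140 by at least 2-fold (edgeR adjusted p under 0.05). Without the med7 libraries the count was 2102, 1188 higher and 914 lower. Leaving out any 1 of the 8 libraries moved it by more than 1.5 times, from 34 without parent replicate 1 to 2091 without med7 replicate 1.

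Of 30 glucose-repressed and galactose genes 9 rose in med10 (11 adjusted over the list alone; 17 without the med7 libraries), with a median of 0.48 (camera adjusted p = 2.46e-05; adjusted p = 0.494 with an estimated correlation). They included HXT4 (1.45), HXT2 (0.96), REG2 (1.30) and the galactokinase gene GAL1 (1.11). Of 135 ribosomal protein genes 12 rose (16 adjusted over the list alone; 69 without the med7 libraries, where 1 fell), with a median of 0.28 (camera adjusted p = 4.35e-10; adjusted p = 0.577 with an estimated correlation). RPL22B (2.04), RPS9A (1.02) and RPL28 (1.02) were among them. Of 8 meiosis and sporulation genes 3 rose, also when adjusted over the list alone: SPS4 (2.95), the meiotic kinase gene IME2 (1.43) and RED1 (1.19), which encodes a protein of the meiotic chromosome axis (median 0.54, camera adjusted p = 0.0106; adjusted p = 0.577 with an estimated correlation). Of 46 respiration genes 5 rose, NDE1 (0.84), HAP4 (1.19), COX12 (0.54) and CIT1 (0.52) among them, and 6 when adjusted over the list alone (median 0.21, camera adjusted p = 0.0189; adjusted p = 0.647 with an estimated correlation). The respiration call was lost without parent replicate 1 (adjusted p = 0.0514) or med10 replicate 2 (0.0509). The fit without the med7 libraries gave 4 and 0 for meiosis and 20 and 4 for respiration genes, higher and lower.

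Of 30 heat shock genes 7 fell in med10 (11 adjusted over the list alone; 16 without the med7 libraries, where 2 rose), with a median of −0.32 (camera adjusted p = 1.25e-05; adjusted p = 0.568 with an estimated correlation). CUR1 (−0.90), the small heat shock gene HSP42 (−0.85), FES1 (−0.79) and APJ1 (−0.61) had the smallest adjusted p. Of 25 iron and copper genes 7 fell and 2 rose (8 and 3 adjusted over the list alone; median −0.16, camera adjusted p = 0.0366; adjusted p = 0.524 with an estimated correlation). FTR1 stood at −1.41, FRE4 at −1.03, TIS11 at −1.48 and the siderophore transporter gene SIT1 at −0.74. The iron call was lost without either med7 library (adjusted p = 0.0821 and 0.0955) and without either med21 library (adjusted p = 0.0547 and 0.0518). Of 17 MATa and pheromone genes STE2 rose (1.53) and 3 fell, the pheromone-induced FUS1 (−1.14), PRM5 (−0.54) and STE12 (−0.56), against 1 and 5 adjusted over the list alone (median −0.53, camera adjusted p = 0.00358; adjusted p = 0.524 with an estimated correlation). The fit without the med7 libraries gave 4 and 11 for iron and copper and 1 and 7 for MATa and pheromone (of 16) genes, higher and lower.

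Shifts in med10 were also called for 81 ribosome biogenesis genes, of which 3 fell, REI1 (−0.60), RLP24 (−0.46) and MAK16 (−0.89), and 0 when adjusted over the list alone (median −0.19, camera adjusted p = 0.000547; adjusted p = 0.577 with an estimated correlation). Of 21 sulfur and methionine genes MET14 fell (−0.71), with 3 adjusted over the list alone (median −0.31, camera adjusted p = 0.00382; adjusted p = 0.662 with an estimated correlation). Of 25 sterol genes ERG7 rose (0.58) and IDI1 fell (−0.55), with 6 and 1 adjusted over the list alone (median 0.21, camera adjusted p = 0.00769; adjusted p = 0.674 with an estimated correlation). Of 50 Gcn4 regulon genes ARG8 rose (0.89), also adjusted over the list alone (median 0.13, camera adjusted p = 0.0366; adjusted p = 0.831 with an estimated correlation), and the call was lost without med10 replicate 1 (adjusted p = 0.0795) and with the length correction (0.0701). Glycolysis and fermentation genes had a median of 0.34 (camera adjusted p = 0.00304; adjusted p = 0.682 with an estimated correlation) and RNA polymerase II and general transcription factor genes a median of −0.21 (camera adjusted p = 0.0140; adjusted p = 0.568 with an estimated correlation), though with all 8 libraries no single member of either passed in edgeR, over all genes or adjusted over the list alone. Of their 19 and 33 members, 3 and 9 had an unadjusted p under 0.05, DESeq2 called 2 and 4, and limma-voom 0 and 0. In the fit without the med7 libraries more members passed, with counts that rose and fell of 4 and 31 for ribosome biogenesis, 1 and 9 for sulfur and methionine, 11 and 1 for sterol, 24 and 3 for Gcn4 regulon, 11 and 0 for glycolysis and fermentation and 2 and 10 for polymerase and general transcription factor genes.

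Among lists not called in med10, TMA10 (−0.94), PNC1 (−0.68) and DDR2 (−1.54) fell among 31 general stress genes, also when adjusted over the list alone, and the list's median (0.07) and mean (−0.07) differed in sign. Of 18 members of the phosphate list GIT1 (1.67), PHO3 (1.01) and CTF19 (1.04), which encodes a kinetochore protein, rose and PHM8 fell (−0.59), with 4 and 2 adjusted over the list alone. SED1 (−0.72) and CCW14 (−0.55) fell among 26 cell wall genes (median −0.02, or 0.00 with RLE scaling, mean 0.04). YHP1 (−0.79) fell among 29 cell cycle genes, a list that passed without med7 replicate 1 (adjusted p = 0.0441), med7 replicate 2 (0.0487) or med10 replicate 1 (0.0331), with library size alone (0.0244) and with the length correction (0.0217), and MED1 (0.65) and SSN8 (0.45) rose and SOH1 (−0.72) fell among 20 Mediator subunit genes. Adjusted over the list alone, the counts that rose and fell were 1 and 4 for cell wall, 0 and 1 for cell cycle, and 2 and 1 for Mediator genes. No histone gene of 11, proteasome gene of 32, endoplasmic reticulum folding gene of 16 or MATalpha marker of 4 passed the edgeR threshold; adjusted over the list alone 1 histone gene rose. Their unadjusted p was under 0.05 for 3, 1, 1 and 1, and the counts were 1, 0, 0 and 0 with DESeq2 and 0, 0, 0 and 2 with limma-voom. In the fit without the med7 libraries the counts that rose and fell were 6 and 5 for general stress, 9 and 4 for phosphate, 7 and 7 for cell wall, 1 and 4 for cell cycle and 3 and 4 for Mediator genes. For the other lists of this paragraph they were 1 and 2 for histone, 1 and 3 for proteasome, 1 and 0 for endoplasmic reticulum folding and 0 and 3 for MATalpha genes.

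**Figure D3:**
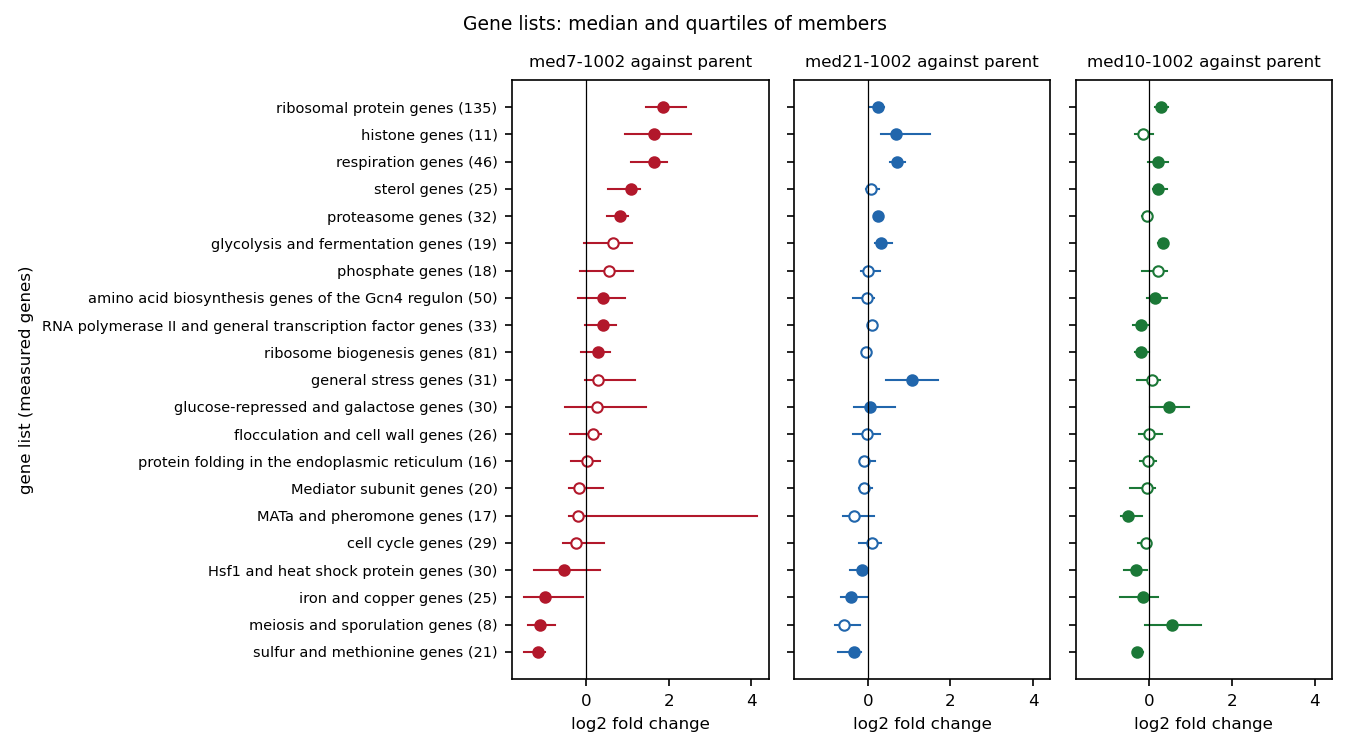
Median log2 fold change against parent of the members of 21 gene lists (points) with the range from the lower to the upper quartile (lines), for each mutant. Filled points mark lists with a camera adjusted p under 0.05 at the preset correlation; with an estimated correlation no list was called, and the ribosomal protein genes have medians of 1.86, 0.25 and 0.28.

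Changes in the same direction in all 3 mutants covered 57 transcripts, 22 higher and 35 lower. Among those higher were the transporter genes PUT4 (5.88, 5.86 and 0.81 in med7, med21 and med10), HXT7 (2.89, 3.30 and 0.84), HXT4 (1.48, 3.37 and 1.45) and HXT2 (1.89, 1.61 and 0.96). Others were the sporulation gene SPS4 (3.01, 2.54 and 2.95), NCA3 (0.99, 2.58 and 2.01), HMS1 (1.81, 2.37 and 1.00), the respiration genes HAP4 (1.13, 2.02 and 1.19) and COX12 (2.40, 1.23 and 0.54), and the ribosomal protein gene RPS17B (3.31, 0.75 and 0.69). Among those lower were the transporter genes QDR2 (−3.43, −2.21 and −1.47) and ATR1 (−2.48, −1.52 and −0.69), the iron genes TIS11 (−2.92, −1.63 and −1.48) and FRE4 (−2.75, −0.46 and −1.03). So were PRY3 (−2.39, −1.88 and −0.81) and SCW11 (−2.07, −1.25 and −0.87), GAT1 (−2.19, −1.56 and −1.32), MNC1 (−2.25, −1.62 and −0.76), LST8, a subunit of the TOR complexes (−2.18, −1.15 and −0.90), and CUR1 (−1.97, −1.29 and −0.90). QDR2 lies on chromosome IX (132240 to 134042, plus strand) and PUT4 on chromosome XV (986720 to 988797, minus strand).

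**Figure D4:**
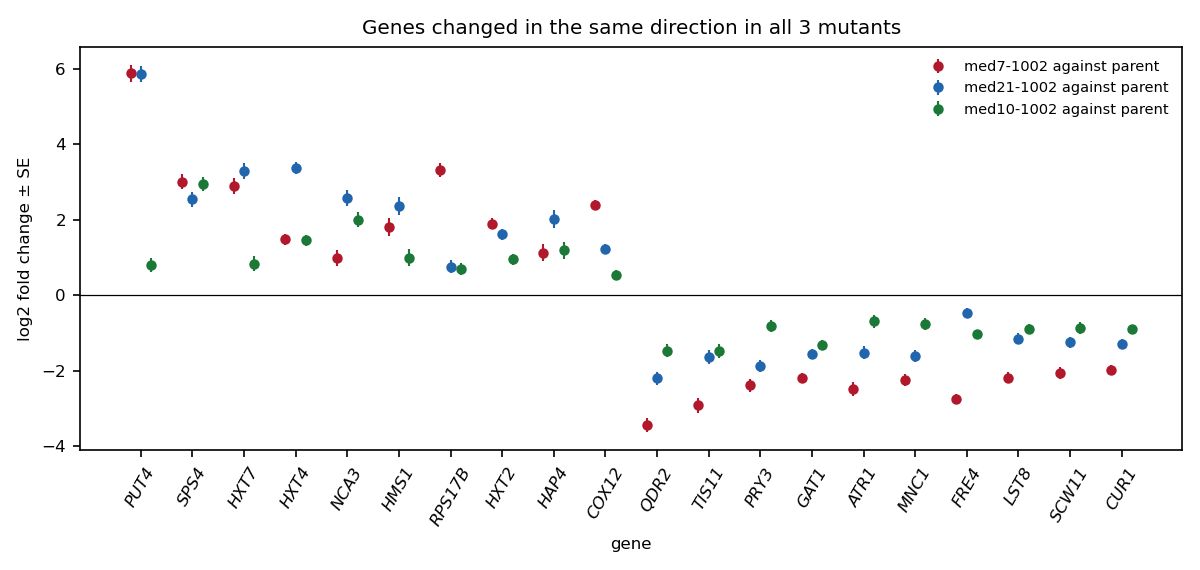
Log2 fold change against parent, with its SE, of the 20 named genes changed in the same direction in all 3 mutants. SPS4 lies near the same value in each mutant (3.01, 2.54 and 2.95), whereas PUT4 stands at 5.88 and 5.86 in med7 and med21 and at 0.81 in med10.

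Independent lists of these sizes would share 2.85 higher and 1.34 lower transcripts, and 50 simulations of unchanged groups against the same parent libraries gave 0 and 0. With no changed transcripts simulated, those zeros do not measure what shared controls add to real calls. The 2 parent libraries serve all 3 comparisons and cannot be split, so part of the excess may come from the shared controls. Leaving out any 1 of the 8 libraries moved the count of 57 by more than 1.5 times, from 6 without parent replicate 1 or med10 replicate 1 to 389 without med7 replicate 1.

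By pairs, med7 and med21 shared 150 higher and 203 lower transcripts, with 26 changed in opposite directions (57.8 and 50.9 for independent lists). Across transcripts, which are not independent replicates, their fold changes had a Pearson r of 0.48 (0.17 in the simulations) and a Spearman rho of 0.54 (0.13), and a covariance of 0.288 against 0.0177 in the simulations. For med7 and med10, 55 were higher and 81 lower in both and 133 moved in opposite directions (73.3 and 34.2 for independent lists), with r = 0.03 (0.20 in the simulations), rho = 0.04 (0.18), and a covariance of 0.0167 against 0.0166 simulated. For med21 and med10, 40 were higher and 41 lower in both and 27 opposite (11.0 and 5.91 for independent lists), with r = 0.17 (0.45 in the simulations), rho = 0.16 (0.36), and a covariance of 0.0493 against 0.0173 simulated. The simulated r and rho cannot be set against the observed ones, because simulated groups hold no changed transcripts and their fold changes spread less. Covariances are not divided by that spread. For opposite changes no number for independent lists was computed, so the counts of 26, 133 and 27 do not show more opposition than such lists would give.

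Tested directly, the med21 mutant exceeded med10 for PUT4 by 5.06 on the log2 scale (SE 0.21, adjusted p = 7.89e-06), HSP12 by 4.81, DDR2 by 4.35, HXT7 by 2.47 and CTT1 by 2.42. It lay below med10 for ARO10 (−3.99), SEO1 (−3.86), SUT116 (−3.44), SUT692 (−3.18) and SUT429 (−3.02). In total 1150 transcripts differed between these mutants, 539 higher and 611 lower in med21. Without the med7 libraries there were 2700, 1278 higher and 1422 lower. Leaving out any 1 of the 8 libraries moved this count by more than 1.5 times, from 295 without med21 replicate 2 to 2751 without med7 replicate 1.

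The med7 mutant exceeded med21 for BAR1 (6.09), MFA2 (6.04), MFA1 (5.75), STE2 (4.78) and URA3 (3.94). It lay below med21 for MF(ALPHA)1 (−9.18), STE3 (−8.72), AFB1 (−5.56), SUT292 (−2.87) and CIP1 (−2.72). In this comparison 2338 transcripts differed, 1269 higher and 1069 lower, or 1079 higher and 1518 lower with library size alone. The count was 1265 without med21 replicate 1 and 3898 without med7 replicate 2. The med7 mutant exceeded med10 for HSP12 (7.09), MFA2 (6.60), MFA1 (6.49), BAR1 (5.19) and PUT4 (5.07), and was lower for MF(ALPHA)1 (−9.09), STE3 (−8.53), AFB1 (−5.41), SEO1 (−5.12) and ARO10 (−4.62). Here 3154 transcripts differed, 1718 higher and 1436 lower, or 1467 higher and 1822 lower with library size alone and 1540 and 1786 with upper-quartile scaling. With library size alone the median over all transcripts moved by −0.11, and without med10 replicate 2 the count was 2080. Per the labels the libraries of these groups carry the same 2 barcodes and no run is given, so a batch difference between them could not be tested.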

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

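The tests in this part were chosen after their results were seen. Reads outside every annotated transcript, which enter no comparison, took a larger share in all 6 mutant libraries than in either parent library, where the higher value was 33.5%. The shares of replicates 1 and 2 were 49.5% and 37.7% in med7, 36.3% and 34.3% in med21, and 34.7% and 34.7% in med10.

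Short transcripts were higher in med7 replicate 1, the library with the largest of these shares and the lowest depth. Against the parent mean, transcripts up to 500 nt had a median log2 difference of 1.06 in replicate 1 and −0.11 in replicate 2, and the 351 longest transcripts −0.50 and −0.14. Short gene groups that rose do not carry this trend, since rho of change with length was −0.474 over 4683 coding transcripts outside the ribosomal protein, respiration, proteasome and histone lists. Nor can the trend be the whole cause of the rise of the ribosomal protein genes, whose median in med7 was 1.55 after the length correction and 1.83 without med7 replicate 1. A length bias of this library that acts on every kind of transcript stays open: rho over 525 noncoding transcripts was −0.187, with a bootstrap interval from −0.278 to −0.0954 that spans the bound of −0.1, which was itself set after the value was seen, and an effect of the allele on transcript ends or decay was not tested.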

How the results depend on the processing

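The fit without the med7 libraries and the length correction were chosen after seeing the data; the other alternatives were planned. Scaling by spike-in totals, also planned, was not run, because spike-in counts were not analysed here. Where 1 library was left out, the lone sample of its group was assumed to vary like the other groups. At the lowest depth, 10962170 counts in med7 replicate 1, 305 transcripts had no read, against 148 to 211 in the others, which limits what can be seen at low levels. No named gene and no gene list changed direction past the threshold under any setting, and each count of changed transcripts per comparison that is not given here stayed within 1.5 times its value. Counts within a list or a noncoding class moved further: in med10 ribosomal protein genes that rose went from 12 to 2 and XUTs that rose from 17 to 7 with the replicate block, and in med21 sulfur genes that fell went from 3 to 9 with upper-quartile scaling and ribosomal protein genes that rose from 7 to 45 without med7 replicate 1. In med7, general stress genes that rose and fell went from 11 and 3 to 11 and 11 without med7 replicate 2, and cell wall genes from 5 and 4 to 5 and 11. The larger side of the split between higher and lower turned in the 3 comparisons with med7 under upper-quartile scaling, library size alone, coding transcripts only, and without parent replicate 2, med7 replicate 2 or med10 replicate 1. It also turned under some settings for the other counts of changed transcripts, except that of med10 against parent. For med7 against parent, 1325 of 2790 changes reached 2-fold, and leaving out 1 library gave 1847 to 3936. For med21 (448), the counts were 766 with DESeq2, 1213 with only the groups compared, 1694 without the med7 libraries, 730 with the length correction, 178 at an adjusted p under 0.01, 186 at 2-fold or more, and 107 to 1695 with 1 library left out. For med10 (434), they were 886, 2997, 2102, 731, 106, 140, and 34 to 2091 in the same order. For med7 and med21 (2338), they were 1322 with only the groups compared, 1357 at an adjusted p under 0.01, 875 at 2-fold or more and 1265 to 3898 with 1 library left out. For med7 and med10 (3154), 1632 reached 2-fold and the range was 2080 to 4150. For med21 and med10 (1150), they were 2379 with only the groups compared, 2700 without the med7 libraries, 422 at an adjusted p under 0.01, 427 at 2-fold or more and 295 to 2751. For all 3 mutants (57), they were 106 with upper-quartile scaling, 109 with library size alone, 133 with DESeq2, 103 with coding transcripts only, 305 with only the groups compared, 126 with the length correction, 14 at an adjusted p under 0.01, 7 at 2-fold or more and 6 to 389. The rise without the med7 libraries goes with their wider replicate spread (median dispersion 0.0553, against 0.00307 in parent); the cause of the other changes was not tested.

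The replicate numbers carry no stated shared day, so no block entered the main fit. In a later check, same-numbered libraries of different groups did not deviate together (correlations of −0.186 to 0.0938 over 6 pairs of groups). With the replicate block the counts were 269 for med21, 202 for med10 and 23 for all 3 mutants. The block ended the call of the Gcn4 regulon list in med7 and med10 (adjusted p = 0.0509 in each), and no other list call. Of 66 list tests 38 were called, 0 with an estimated correlation (6 with an unadjusted p under 0.05; also 0 with the length correction) and 26 with fry, which tests against no change. Leaving out 1 library gave 35 to 38. With scaling, the length correction or a library left out, these list calls were lost at least once: heat shock in med7 and med21, ribosome biogenesis and meiosis in med7, Gcn4 regulon in med7 and med10, glucose-repressed in med21, and iron and respiration in med10. Lists gained at least once under the same settings were general stress and glycolysis in med7, cell cycle in med21 and med10, sterol, MATa and polymerase in med21, and glucose-repressed in med7; fry, with its other hypothesis, called glucose-repressed and MATa in med7.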

Other observations

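The tests in this part were chosen after their results were seen. The noncoding classes moved differently in the mutants. In med10, 57 of 378 SUTs rose and 1 fell, with a median log2 fold change of 0.49, and 17 of 351 XUTs rose and 2 fell (median 0.27). In med21, 4 SUTs rose and 27 fell (median −0.44), and in med7, 5 rose and 114 fell (median −0.54), where 8 XUTs rose and 75 fell. The 2 med7 libraries disagree on this: against the parent mean, the median log2 differences in replicates 1 and 2 were −0.31 and −1.01 for SUTs, −0.11 and −1.07 for XUTs, and 0.53 and −0.89 for CUTs, so that without a length correction the fall rests mostly on replicate 2. Among transcripts up to 1000 nt, coding ones stood at 0.84 and 0.50 in replicates 1 and 2, and noncoding ones lower, at 0.18 and −0.94. After the length correction 138 SUTs fell and 5 rose in med7 (median −0.79). For XUTs 99 fell and 8 rose (median −0.74), and for CUTs 19 fell and 1 rose (median −0.64). The correction takes off a trend fitted mostly over coding transcripts, from which short noncoding ones differed. The CUT median in med7 was 0.03 before it, so the corrected falls may come in part from the correction. Tested directly, 126 SUTs were lower and 2 higher in med21 than in med10. SUTs took 0.928% and 0.997% of the counts in med10, 0.626% and 0.682% in parent, 0.484% and 0.473% in med21, and 0.401% and 0.244% in med7. Without the med7 libraries 164 SUTs rose and 20 fell in med10, and 12 rose and 120 fell in med21. The same fit gave 83 XUTs higher and 22 lower in med10, whereas with the replicate block 7 rose and 1 fell.

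Coding genes within 20 kb of a chromosome end also went opposite ways. Of 90 such genes 24 fell and 4 rose in med21 (31.1% changed, against 8.29% of 4907 coding genes), and the 15 that changed in med10 were higher (16.7% against 7.28%). Fisher's exact test, two-sided and over genes that are not independent, gave p = 2.70e-10 and 0.00292. In med7, 44 of these genes fell and 8 rose, against 1098 that fell and 1473 that rose of the 4907 coding genes. Their median log2 fold change was −0.52, against 0.07 over coding genes. The share of changed genes in med7 was 57.8% against 52.4% (Fisher's exact test, p = 0.338). These Fisher tests compare the share changed in either direction, so they do not test the direction. The window was chosen after the values were seen.

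The length trend does not account for the SUT pattern of med10, whose median was 0.517 after the length correction. A smaller share of unlabelled stable RNA in the med10 libraries would raise CUTs, which are short-lived. It would raise SUTs too only if they are short-lived, and their lifetimes were not measured here. The 34 CUTs with a mean log2 CPM above 1 had a median of −0.398 (bootstrap interval −0.555 to −0.141), but −0.278 after the length correction, with an interval from −0.445 to 0.00923 that includes 0, so this explanation stays open. In med21 the same 34 CUTs had a median of −0.428 (interval −0.616 to −0.241), and −0.416 (interval −0.579 to −0.163) after the length correction. This is the direction of its SUTs, so a larger share of unlabelled stable RNA in those libraries may account for their fall. An effect of the alleles on noncoding transcription stays open and was not tested. For med7 a different share of unlabelled RNA was not tested either, neither for noncoding transcripts nor for the gene lists that rose.

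For the mating-type genes of the med7 libraries, a mixture of both mating types in those cultures is argued against by the alpha-specific genes, whose median level was 0.995% of the parent mean and whose highest, that of SAG1, was 18.4%. Loss of repression of a-specific genes by the allele alone would leave alpha-specific genes near the parent level, but their median log2 fold change was −7.41. Cells of the other mating type than in the other 3 groups are a candidate explanation. Of the 10 measured specific genes 9 passed the threshold in the direction this needs. The same genes prompted the explanation, so that count is not a test of it. The genotype labels read MATa throughout, so this hypothesis puts the labels of parent, med21 and med10, rather than that of med7, at odds with the counts. It would also mean that strain background and allele cannot be separated in any comparison with med7.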
